A study of Mus musculus with 9 samples.

How the data were processed

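Gene expression was measured by RNA sequencing in 9 libraries of transfected TC2R mouse prostate cancer cells, 3 per group, with RNA extracted with the RNeasy kit per the labels' protocols. The deposited values are raw read counts per gene, 1 column per library, with whole numbers and differing totals. The submitters' processing notes name FastQC, STAR (version 1.5.1), featureCounts, Subread (1.6.1) and edgeR (3.22.5) and the mm10 genome build, with no roles or order; whether 1.5.1, printed there beside STAR, is that tool's version is uncertain. The annotation, the strand setting, the treatment of reads that map to several places, and the way RNA was selected before library preparation are not given in the sources used here. Genes that overlap, or that lie antisense to each other, may therefore share counts, and reads of near-identical copies may have been dropped or split. Every gene in the deposited count table reached about 0.5 CPM in at least 3 libraries (lowest such value 0.500556) and a total of at least 99 reads, so genes of low count appear to have been removed before deposit; this was inferred from the values. Each column name matched the label of a single sample, and groups and replicate numbers were taken from the labels.

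Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 9 libraries entered 1 fit with the group as the only term, TMM normalization and edgeR's quasi-likelihood test, so that the 3 groups shared the estimate of spread. P-values were adjusted by the Benjamini-Hochberg method over the 12125 genes tested, and a gene passed at an adjusted p under 0.05. The filter on low counts (filterByExpr) removed 0 genes. The common biological coefficient of variation was 5.76%. Comparisons were IL27_scr and IL27_pepL each against plasmid control, IL27_pepL against IL27_scr, and the mean of both IL-27 groups against plasmid control. CPM values use library sizes scaled by the TMM factors. The standard error of a log2 fold change is its size divided by the square root of the test's F statistic. Ratios of transgene counts to the 2 or 3 control reads carry exact 95% intervals for the ratio of counts, which cover counting error only, since sequenced fragments are not independent molecules.

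The 29 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The 26 lists with at least 5 measured genes were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. For each list the members past the test were counted over all genes and adjusted over the list alone. For 1 of the tested lists the results are not reported here. The rule named, in each pairwise comparison, Il27, Ebi3, Il27ra, Il6ra and Il6st; the 8 highest and 8 lowest fold changes among called genes with a mean of at least 1 CPM and groups that did not overlap; up to 4 called members of each list by smallest p, or 2 members where none was called; and, where fewer than 5 genes passed, the 5 with the smallest p. Predicted genes were passed over. Gene positions come from an mm10 annotation, which placed 12040 of the 12125 genes; Rn45s has no position in it.

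Alternatives were DESeq2 size factors, no filter, a filter of at least 1 CPM in 3 libraries (which removed 633 genes), DESeq2's Wald test (version 1.42.0), limma-voom, a fit of only the compared groups, replicate number as an added term, removal of Il27 and Ebi3, and omission of each library in turn. A per-library offset for transcript length and GC content and removal of Rn45s were added after seeing the data. Length and GC content were those of each gene's longest annotated transcript, known for 99.5% of genes. For groups that share libraries, correlations and shared calls were set beside 100 simulations of unchanged groups. The procedure was tested on simulated counts for the 12125 genes. Changed genes were drawn from those with a mean of at least 1 CPM. Genes were simulated as independent and without a length and GC trend, so recovery in the real counts may be lower. For IL27_pepL against plasmid control edgeR recovered 82% of genes changed 1.25-fold, 86% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 6 false calls of 188; for IL27_pepL against IL27_scr it recovered 78%, 88%, 94% and 100%, with 8 false of 188. In the comparison simulated without change it made 0 calls and DESeq2 made 4. In the simulated IL27_pepL against IL27_scr comparison the 1 list moved 1.25-fold passed camera with either correlation, and 1 unmoved list passed the preset test falsely.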

Results

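RNA was sequenced from TRAMP-C2-Ras (TC2R) cells, a mouse prostate adenocarcinoma line made from TRAMP-C2 cells by lentiviral delivery of activated H-ras and of the mouse androgen receptor. Cells were transfected for 6 h with 1.5 µg of plasmid DNA and 2 µL of Lipofectamine per well and were collected 24 h after the start of transfection. The 9 libraries fell into 3 groups of 3: an empty expression plasmid (plasmid control), a plasmid encoding IL-27 with a non-specific peptide (IL27_scr), and a plasmid encoding IL-27 with a peptide directed at the IL-6 receptor alpha chain (IL27_pepL). IL-27 is a cytokine made of the Il27 and Ebi3 chains that signals through Il27ra and Il6st (gp130). The deposited table held raw read counts for 12125 genes. Total counts per library ranged from 27609884 to 35078027 in plasmid control, from 30087806 to 35959983 in IL27_scr and from 30013229 to 34164353 in IL27_pepL. Within groups, log2 CPM values correlated across genes with r from 0.993 to 0.997, and each pair differed by more than sampling noise, with a chi-square per degree of freedom from 3.04 to 32.8. The widest pair was IL27_pepL replicates 1 and 3, and replicate 3 lay farthest out on the first principal component, which held 32.4% of the variance. Nothing in the labels says whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

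The transfected transcripts were read in both IL-27 groups and were nearly absent from the plasmid control. The annotated Il27 gene (chromosome 7, 126589010 to 126594941, minus strand, mm10) received 179 to 244 reads per IL27_scr library and 237 to 252 per IL27_pepL library, against 2 reads in all plasmid control libraries together. Ebi3 (chromosome 17, 55952640 to 55957022, plus strand) received 266 to 269 reads per IL27_scr library and 314 to 419 per IL27_pepL library, against 3 in the plasmid controls. Scaled for depth, the Il27 ratio to plasmid control was 300.4 (95% counting interval 82.8 to 2486) in IL27_scr and 350.3 (96.6 to 2898) in IL27_pepL; for Ebi3 it was 245 (83.6 to 1191) and 351 (120 to 1703). These intervals cover counting error only, and reads from the plasmids and from the endogenous genes cannot be told apart in these counts. Mean Il27 was 6.47 ± 0.50 CPM (SD, n = 3) in IL27_scr and 7.62 ± 0.76 CPM in IL27_pepL, and mean Ebi3 was 8.0 ± 0.76 and 11.5 ± 2.5 CPM. Between the IL-27 groups the log2 fold change was 0.23 ± 0.11 (SE) for Il27 and 0.52 ± 0.14 for Ebi3, and neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.236 and 0.0697).

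The receptor genes were all measured. In the plasmid control, IL-27 receptor alpha, Il27ra (chromosome 8, 84030294 to 84042589), stood at 2.62 ± 0.31 CPM, the targeted receptor Il6ra (chromosome 3, 89864059 to 89913196) at 16.4 ± 1.3 CPM, and the shared signalling chain Il6st (chromosome 13, 112464070 to 112510086) at 172 ± 4.4 CPM. None of them passed the edgeR test in any comparison. The smallest adjusted p among these was 0.0647, for Il6st in IL27_pepL against plasmid control, with a log2 fold change of -0.18 ± 0.04.

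**Figure D1:**
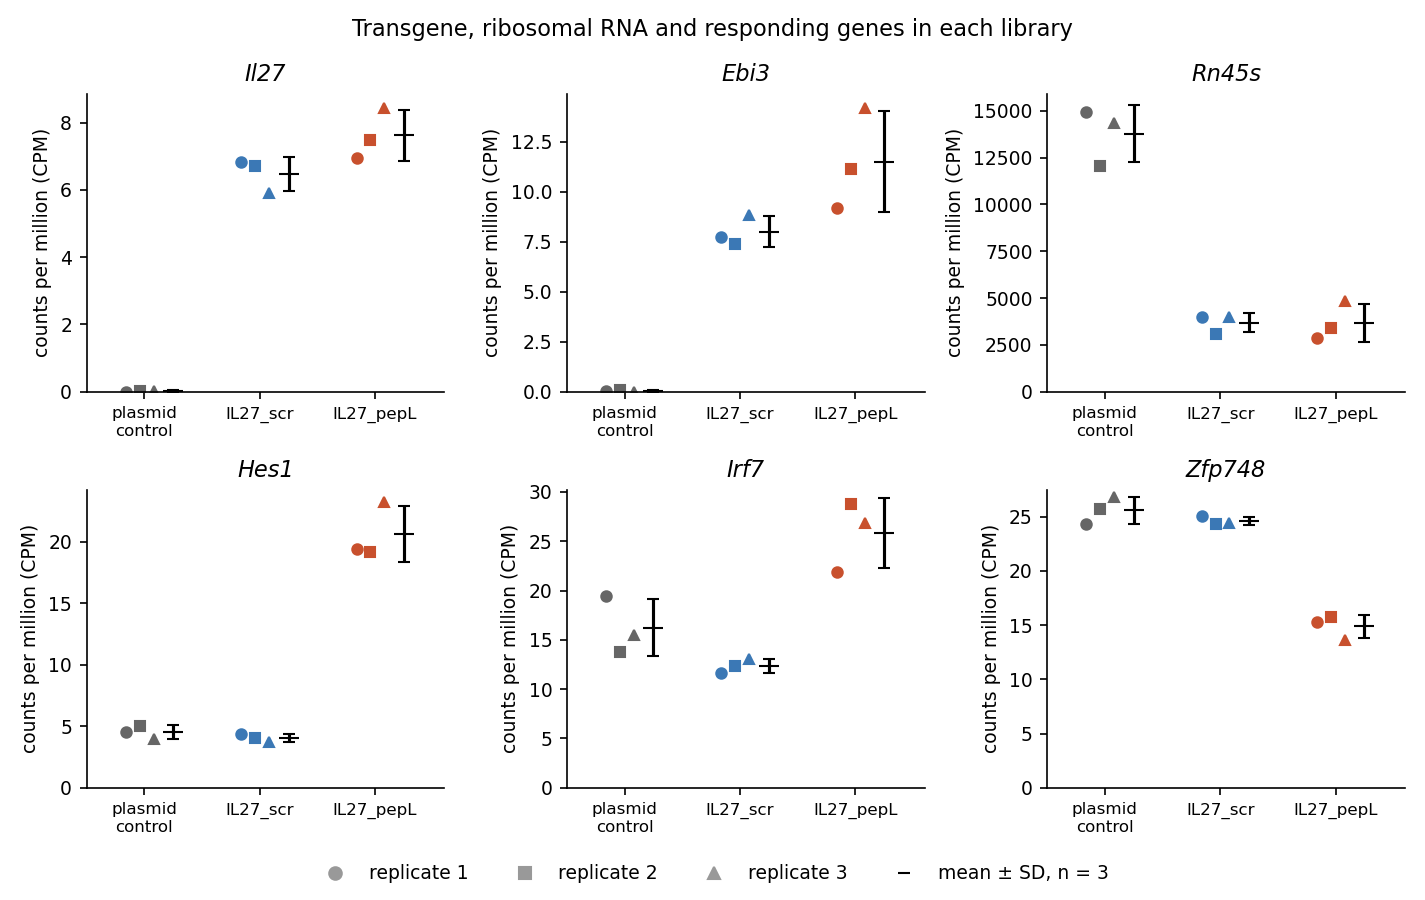
CPM of Il27, Ebi3, Rn45s, Hes1, Irf7 and Zfp748 in each of the 9 libraries; points are libraries, bars the group mean and SD (n = 3). Il27 and Ebi3 were read in both IL-27 groups, Rn45s was lower in both than in plasmid control, and Hes1 was at 20.6 CPM in IL27_pepL against 4.52 and 4.05 CPM in the other groups.

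The first comparison, IL27_scr against plasmid control, asked what IL-27 with the non-specific peptide did to these cells. Apart from the transgenes, 1 gene changed: Rn45s, the precursor of ribosomal RNA, fell by 1.90 ± 0.16 on the log2 scale (edgeR adjusted p = 1.01e-04), from 1.37% ± 0.148 of all counts (SD, n = 3) to 0.373% ± 0.0522. Il27 and Ebi3 rose (adjusted p = 1.40e-08 and 1.76e-07). These 3 were the calls among 12125 genes, 2 higher and 1 lower, and each was kept when any library was left out. At an unadjusted p under 0.05 there were 312 genes (2.57%), DESeq2's Wald test called 4 and limma-voom 3. Among the remaining genes, with predicted genes passed over, the smallest p-values belonged to the scaffold protein gene Akap9 (log2 fold change -0.32 ± 0.07, edgeR adjusted p = 0.798) and the mitochondrial leucyl-tRNA synthetase gene Lars2 (-0.68 ± 0.14, adjusted p = 0.798).

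No member of any fixed gene list passed in IL27_scr against plasmid control. Type I interferon-stimulated genes had a median log2 fold change of -0.21, with 1 of 32 above 0; Parp14 was at -0.35 ± 0.09 and Oasl2 at -0.30 ± 0.09 (edgeR adjusted p = 0.999 for both). Camera with its preset inter-gene correlation placed 6 of 26 lists apart from the other genes. Among these were interferon-stimulated genes (lower, adjusted p = 2.01e-21), nucleic acid sensing genes (lower, 0.0313), mesenchymal and matrix genes (lower, 0.00265), replication-dependent histone genes (lower, median -0.23, 3.37e-06) and STAT3 and IL-6 response genes (higher, median 0.05, 0.0164). With an estimated correlation 0 of the 26 passed, and the lowest adjusted p was 0.465; fry also gave 0. Adjusted over the list alone, 1 member was called in each of the nucleic acid sensing, histone and immune checkpoint lists, all lower, and 0 in the others. Without plasmid control replicate 1 the preset test gave 3 lists in place of 6. The nucleic acid sensing and mesenchymal lists then had adjusted p = 0.404 and 0.227; without IL27_scr replicate 2 these were 0.345 and 0.0971. Without IL27_scr replicate 1 the STAT3 list had 0.154, and without plasmid control replicate 2 the STAT3 list had 0.0997.

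The second comparison, IL27_pepL against plasmid control, asked the same of IL-27 with the targeting peptide. Among genes that the naming rule admits, the highest rise after the transgenes was that of Hes1, a transcriptional repressor (chromosome 16, 30064384 to 30067796, plus strand). Hes1 went from 4.52 ± 0.56 to 20.6 ± 2.3 CPM (SD, n = 3), 4.54-fold (log2 fold change 2.18 ± 0.11, edgeR adjusted p = 1.74e-07). The acute-phase genes Saa3 and Lcn2 rose 1.99-fold and 1.93-fold (adjusted p = 0.0314 and 0.0205), and the interferon regulator Irf7 rose 1.58-fold, from 16.2 ± 2.9 to 25.8 ± 3.5 CPM (0.0199). Immediate early gene Egr1 rose 1.61-fold (0.00207). Rn45s again fell by 1.90 ± 0.16 (7.49e-05), to 0.364% ± 0.0977 of counts, and the zinc finger gene Zfp748 fell to 0.582 of its control level (log2 -0.78 ± 0.07, 1.02e-04).

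Members of several fixed lists changed in IL27_pepL against plasmid control. Of 32 interferon-stimulated genes 9 rose and 23 did not pass (24 higher when adjusted over the list alone). Bst2, an antiviral membrane tether, rose by 0.51 ± 0.09 on the log2 scale (edgeR adjusted p = 0.0196), and Ifit3b and the nucleic acid sensor Zbp1 rose by 0.68 ± 0.13 and 0.58 ± 0.11 (0.0205 for both). The GTPase genes Gbp2 and Gbp3 rose as well (0.48 ± 0.08 and 0.50 ± 0.09; adjusted p = 0.0118 and 0.0158). Of 20 MHC class I genes 3 rose, the peptide transporter Tap1, the light chain B2m and the proteasome activator Psme1 (0.47 ± 0.10, 0.27 ± 0.06 and 0.31 ± 0.06; adjusted p = 0.0317, 0.0334 and 0.0298), with 10 adjusted over the list alone. Of 20 nucleic acid sensing genes Irf7 and Zbp1 rose (4 adjusted over the list alone), and both are also members of the interferon list. Of 24 STAT3 and IL-6 response genes Saa3 and Lcn2 rose, whereas Socs3, a feedback inhibitor of that pathway, fell (-0.35 ± 0.08, adjusted p = 0.0438); adjusted over the list alone there were 2 higher and 3 lower.

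The MAPK output and immediate early list held 25 genes, of which Egr1 and the phosphatase gene Dusp1 rose (Dusp1 0.58 ± 0.06, edgeR adjusted p = 3.23e-04) and the phosphatase gene Dusp6 fell (-0.29 ± 0.05, 0.0104), with 4 higher and 5 lower adjusted over the list alone. Among NF-kB targets the chemokine gene Ccl5 rose (0.54 ± 0.10, 0.0199) and Tnfaip3, an inhibitor of NF-kB signalling, fell (-0.54 ± 0.05, 3.38e-04), and 22 of 24 did not pass (1 higher and 1 lower adjusted over the list alone). The matrix genes Ctgf and Cyr61 rose (0.42 ± 0.04 and 0.37 ± 0.05; 4.93e-04 and 0.00267), the other 26 mesenchymal genes did not pass, and adjusted over the list alone there were 2. In the remaining lists Lgals9, an immune regulatory lectin, rose (0.40 ± 0.06, 0.0102), and the p53 target Eda2r, the caspase regulator Cflar and the linker histone gene Hist1h1e fell (-0.39 ± 0.09, -0.34 ± 0.08 and -1.21 ± 0.26; 0.0440, 0.0447 and 0.0376). No member passed among the ribosomal protein genes, although all 75 lay above 0 (median 0.27) and 62 passed adjusted over the list alone; their median was 0.12 with an offset for transcript length and GC content and 0.18 without IL27_pepL replicate 3. That group's mean log2 CPM was 8.91 ± 0.05 in plasmid control and 8.95, 9.22 and 9.33 in IL27_pepL replicates 1 to 3. Hypoxia and glycolysis genes also had 0 of 24 past the test, with Ldha at 0.21 ± 0.06 (adjusted p = 0.0858) and 9 higher and 2 lower adjusted over the list alone. Among genes that the naming rule admits, the lowest fold changes also took in Lrriq3, the splicing regulator Srrm4, Zfp747, the transposase-derived Tigd5 and the zinc finger gene Rbak. Their log2 fold changes were -0.85 ± 0.16, -0.76 ± 0.11, -0.72 ± 0.09, -0.72 ± 0.13 and -0.71 ± 0.11 (edgeR adjusted p = 0.0205, 0.00695, 0.00267, 0.0199 and 0.010).

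In all, 197 of 12125 genes passed in IL27_pepL against plasmid control, 52 higher and 145 lower, and 7 of these had an absolute log2 fold change of at least 1. DESeq2's Wald test called 774, limma-voom 175 and a fit of only the compared groups 48. The count was 55, 36 and 38 without plasmid control replicates 1, 2 and 3, 127 and 110 without IL27_scr replicates 2 and 3, and 2084 and 55 without IL27_pepL replicates 1 and 2. Of the 33 genes named in this comparison that passed, 12 passed whichever library was left out (Il27, Ebi3, Hes1, Rn45s, Egr1, Dusp1, Ctgf, Cyr61, Tnfaip3, Srrm4, Zfp747 and Zfp748), and none changed sign. The calls lost numbered 11, 20 and 18 without plasmid control replicates 1, 2 and 3, 4, 7 and 7 without IL27_scr replicates 1, 2 and 3, and 18 and 6 without IL27_pepL replicates 2 and 3; without IL27_pepL replicate 2, 0 of the interferon-stimulated genes passed. Without IL27_pepL replicate 1, 23 interferon-stimulated genes and 64 ribosomal protein genes passed. The fit of only the compared groups ended 16 of the 33 calls: B2m, Ccl5, Cflar, Dusp6, Eda2r, Gbp3, Ifit3b, Irf7, Lcn2, Lrriq3, Psme1, Saa3, Socs3, Tap1, Tigd5 and Zbp1. Limma-voom ended those of Eda2r, Hist1h1e and Socs3, DESeq2 those of Hist1h1e and Lrriq3, the filter at 1 CPM that of Eda2r, and the length and GC offset those of B2m and Eda2r.

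Camera with the preset correlation placed 7 of 26 lists apart in IL27_pepL against plasmid control. The higher ones included interferon-stimulated genes (median log2 fold change 0.35, adjusted p = 2.43e-18), MHC class I genes (1.03e-06), nucleic acid sensing genes (0.0210), hypoxia and glycolysis genes (6.67e-04) and ribosomal protein genes (4.45e-22). Replication-dependent histone genes were lower (median -0.17, 0.0210). None passed with an estimated correlation, where the adjusted p was 0.412 for the interferon-stimulated and MHC class I lists, 0.522 for the sensing and ribosomal protein lists and 0.639 for the hypoxia and histone lists. The number of lists was 11 without plasmid control replicate 3 or IL27_pepL replicate 3 and 4 without IL27_pepL replicate 1. Without IL27_pepL replicate 1 the sensing, hypoxia and histone lists had adjusted p = 0.0681, 0.0681 and 0.510, and without IL27_pepL replicate 2 the sensing and histone lists had 0.0775 and 0.0621.

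**Figure D2:**
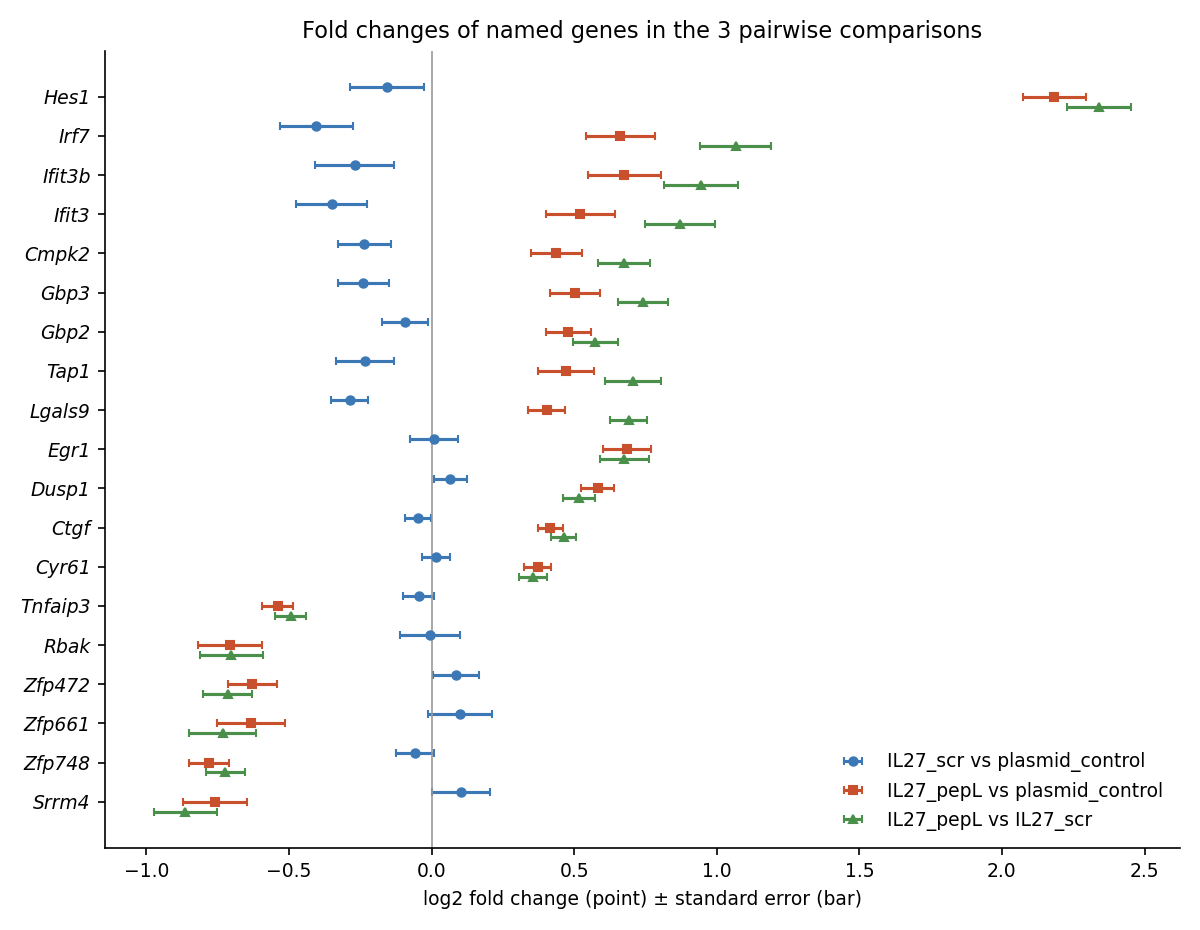
Log2 fold change with SE (n = 3 per group) of 19 genes in IL27_scr and IL27_pepL against plasmid control and in IL27_pepL against IL27_scr. Hes1 was at 2.18 and 2.34 in the comparisons with IL27_pepL and at -0.16 in IL27_scr against plasmid control.

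The third comparison set IL27_pepL against IL27_scr, which differ in the peptide, and is the direct test of whether the plasmids' effects differed. Hes1 was 5.06-fold higher with the targeting peptide (log2 fold change 2.34 ± 0.11, edgeR adjusted p = 2.22e-07; 4.05 ± 0.36 against 20.6 ± 2.3 CPM, SD, n = 3). Of 32 interferon-stimulated genes 26 were higher, 0 were lower and 6 did not pass (28 adjusted over the list alone). As a list they had an adjusted p = 0.114 with an estimated correlation, and their median of 0.57 set -0.21 in IL27_scr against 0.35 in IL27_pepL, each relative to plasmid control. Irf7 (chromosome 7, 141262706 to 141266481, minus strand) was 2.09-fold higher (0.00139), and Ifit3b, Ifit3 and Cmpk2 had log2 fold changes of 0.94 ± 0.13, 0.87 ± 0.12 and 0.67 ± 0.09 (0.00313, 0.00338 and 0.00304). The antiviral synthetase gene Oas2 rose by 0.85 ± 0.18 (0.0241) and Phf11d by 0.83 ± 0.10 (0.00208). Reads of the near-identical Ifit3 and Ifit3b, and of the Oas and Gbp families, may be split between copies, so their single values are uncertain.

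Further immune genes rose with the targeting peptide. The GTPase genes Gbp3, Gbp2, Iigp1 and Irgm1 rose (0.74 ± 0.09, 0.57 ± 0.08, 0.75 ± 0.13 and 0.49 ± 0.09; edgeR adjusted p = 0.00139, 0.00309, 0.0112 and 0.0146). Of 20 MHC class I genes 7 rose, among them Tap1, B2m, the peptide-loading chaperone Tapbp and Psme1 (0.71 ± 0.10, 0.33 ± 0.06, 0.29 ± 0.06 and 0.31 ± 0.06; 0.00338, 0.00947, 0.0156 and 0.0205), with 10 adjusted over the list alone. Of 20 nucleic acid sensing genes 5 rose, with Ifi204 at 0.36 ± 0.05, the RNA sensor gene Ddx58 at 0.43 ± 0.07 and Zbp1 at 0.61 ± 0.11 (0.00393, 0.00888 and 0.0112), and 5 adjusted over the list alone. Of the sensing calls, Irf7, Ddx58 and Zbp1 are also members of the interferon list. As lists, MHC class I and sensing genes had a camera adjusted p = 0.114 and 0.188 with an estimated correlation. Immune checkpoint and regulatory ligands went both ways: of 16, Lgals9 rose (0.69 ± 0.06, 2.98e-04) and Pvr fell (-0.29 ± 0.06, 0.0195), with 3 higher and 1 lower adjusted over the list alone.

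Growth factor and cytokine pathway genes went both ways between the peptides. Of 25 MAPK output genes Egr1 and Dusp1 rose (0.68 ± 0.09 and 0.52 ± 0.06; edgeR adjusted p = 0.00208 and 0.00120) and 3 fell, among them Dusp6 and the growth factor gene Hbegf (-0.24 ± 0.05 for both; 0.0162 and 0.0298), with 5 higher and 4 lower adjusted over the list alone. Of 24 STAT3 and IL-6 response genes the cytokine gene Lif and the oncogene Myc fell (-0.32 ± 0.06 and -0.26 ± 0.06; 0.0146 and 0.0491), with 3 higher and 5 lower adjusted over the list alone; Saa3 and Lcn2 were at 0.69 ± 0.20 and 0.51 ± 0.17 without passing (0.0763 and 0.106). Of 28 mesenchymal and matrix genes Ctgf and Cyr61 rose (0.46 ± 0.04 and 0.36 ± 0.05; 2.98e-04 and 0.00304; 7 adjusted over the list alone). Of 24 NF-kB targets Tnfaip3 fell (-0.49 ± 0.05, 0.00120; 4 higher and 1 lower adjusted over the list alone), and of 19 receptor, kinase and STAT genes the IL-11 receptor gene Il11ra1 rose (0.35 ± 0.08, 0.0434; 2 higher and 2 lower adjusted over the list alone).

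Stress lists held few calls between the peptides. Slc7a11, the cystine transporter counted under both ATF4 targets and NRF2 targets, fell by 0.46 ± 0.10 (edgeR adjusted p = 0.0275), and the other 23 ATF4 targets and 19 NRF2 targets did not pass; adjusted over the list alone there were 0 higher and 4 lower, and 5 higher and 1 lower. The unfolded protein sensor gene Ern1 fell (-0.31 ± 0.07, 0.0277) and was the single call among 29 ER stress genes, also adjusted over the list alone. Eda2r fell among 20 p53 targets (-0.44 ± 0.09, 0.0191; 2 lower adjusted over the list alone), Casp12 rose among 27 apoptosis and necroptosis regulators (0.30 ± 0.07, 0.0487; 1 adjusted over the list alone), and Pfkfb3 fell among 24 hypoxia and glycolysis genes (-0.27 ± 0.06, 0.0384; 7 higher and 1 lower adjusted over the list alone). Of 75 ribosomal protein genes Rpl41 rose (0.55 ± 0.13, 0.0467), all 75 lay above 0, and 66 passed adjusted over the list alone; Rpl41 has near-identical copies in the genome. Mean log2 CPM of that group was 8.90 ± 0.13 in IL27_scr and 9.16 ± 0.20 in IL27_pepL, where IL27_pepL replicate 3 stood highest. Among genes that the naming rule admits, the lowest fold changes were those of Zfp941, Srrm4, Ptprq, Zfp599, Zfp661, Zfp748, Zfp472 and Rbak, from -0.90 ± 0.18 to -0.70 ± 0.11. Of these 8, 6 encode zinc finger proteins whose related sequences make their single values uncertain. Il20rb (0.90 ± 0.21, 0.0423) and the small nucleolar RNA Snora65 (1.08 ± 0.18, 0.00896) were also higher.

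Lists with no member past the test between the peptides, in edgeR, were G2/M cell cycle (25 genes, camera adjusted p = 0.539), DNA replication and S phase (30 genes, 0.998), cholesterol biosynthesis (24 genes, 0.121), heat shock (17 genes, 0.257), androgen response (11 genes, 0.501), epithelial genes (6 genes, 0.998), bone remodelling (6 genes, 0.998) and histones (26 genes, 0.998). Markers of other cell types were few: 5 of 18 macrophage genes were in the table (camera adjusted p = 0.998), with Cd68 at 6.34 ± 0.50, 6.83 ± 0.20 and 7.38 ± 0.50 CPM in plasmid control, IL27_scr and IL27_pepL. The lymphocyte list had 1 of 18 genes in the table, Lck, at 4.82 ± 0.53, 4.63 ± 0.41 and 5.10 ± 0.54 CPM, and the endothelial and muscle list 3 of 16, with Kdr at 4.93 ± 0.94, 5.81 ± 0.56 and 4.17 ± 1.2 CPM. None of these markers passed in a pairwise comparison. Mitochondrially encoded genes had 0 members in the table used here. Adjusted over the list alone, 1 bone remodelling gene was called between the peptides, and 0 in the other lists of these groups.

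In all, 306 of 12125 genes passed between the peptides, 132 higher and 174 lower with the targeting peptide, 5 of them with an absolute log2 fold change of at least 1. DESeq2's Wald test called 811, limma-voom 296 and a fit of only the compared groups 165. The count was 197 without plasmid control replicate 1, 72, 69 and 94 without IL27_scr replicates 1, 2 and 3, and 1782 and 89 without IL27_pepL replicates 1 and 2. Of the 46 genes named in this comparison that passed, 21 passed whichever library was left out, and none changed sign; these were Hes1, Irf7, Ifit3, Ifit3b, Cmpk2, Phf11d, Gbp2, Gbp3, Tap1, Ifi204, Lgals9, Egr1, Dusp1, Ctgf, Cyr61, Tnfaip3, Srrm4, Rbak, Zfp472, Zfp661 and Zfp748. The calls lost numbered 25, 22 and 17 without IL27_scr replicates 1, 2 and 3, 22 and 8 without IL27_pepL replicates 2 and 3, and 9, 3 and 6 without plasmid control replicates 1, 2 and 3. Interferon-stimulated genes past the test numbered 15 without IL27_pepL replicate 2, and ribosomal protein genes 65 without IL27_pepL replicate 1 and 9 with the length and GC offset. The fit of only the compared groups ended the calls of Casp12, Il11ra1, Il20rb, Myc, Pfkfb3, Psme1 and Rpl41. Myc was also lost with DESeq2 size factors and with the filter at 1 CPM, Rpl41 with limma-voom, Il20rb and Zfp941 with DESeq2, Ptprq with the offset, and Casp12 without Rn45s.

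Camera with the preset correlation placed 8 of 26 lists apart between the peptides. Higher in IL27_pepL were, among others, interferon-stimulated genes (median log2 fold change 0.57, adjusted p = 1.91e-44), MHC class I genes (0.27, 4.95e-09), nucleic acid sensing genes (0.09, 1.24e-04), ribosomal protein genes (0.27, 1.98e-23), mesenchymal genes (0.12, 0.00212) and hypoxia and glycolysis genes (0.13, 0.00274), whose single called member, Pfkfb3, was lower. ATF4 targets were lower (-0.09, 0.0195). With an estimated correlation none passed: the adjusted p was 0.114 for the interferon-stimulated and MHC class I lists, 0.188 for sensing, 0.574 for ribosomal proteins, 0.580 for mesenchymal genes, 0.751 for hypoxia and 0.860 for ATF4 targets. The directional fry test, which does not compare a list with other genes, passed 5 lists, among them the interferon-stimulated and MHC class I lists at an adjusted p = 0.0121 and the sensing and checkpoint lists at 0.0128. Without IL27_pepL replicate 1 the preset test passed 5 lists; the ATF4, hypoxia and mesenchymal lists then had adjusted p = 0.789, 0.166 and 0.230, and without IL27_scr replicate 2 the ATF4 list had 0.186.

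**Figure D3:**
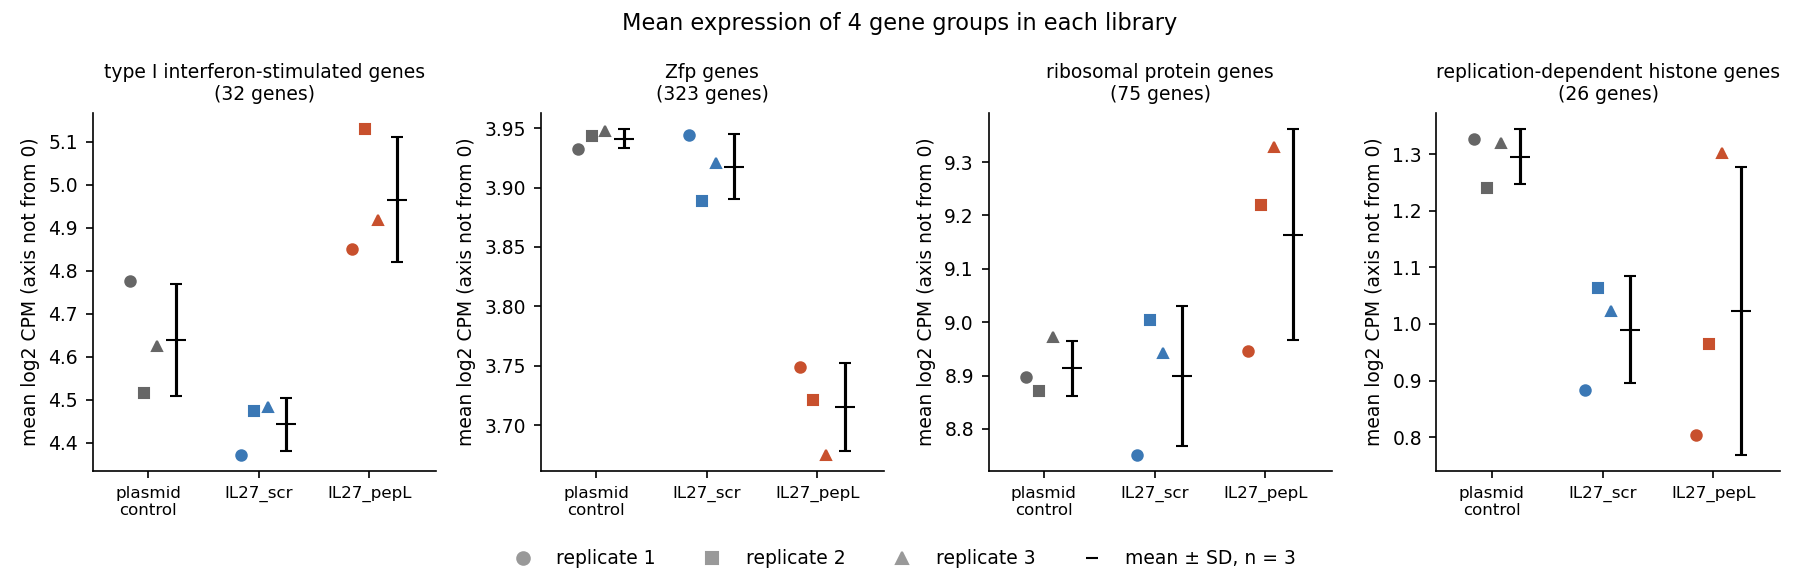
Mean log2 CPM per library of the interferon-stimulated, Zfp, ribosomal protein and replication-dependent histone genes, with group mean and SD (n = 3). Interferon-stimulated genes averaged 4.64, 4.44 and 4.97 in plasmid control, IL27_scr and IL27_pepL, and ribosomal protein genes were at 9.33 in IL27_pepL replicate 3.

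The last comparison took both IL-27 groups together against plasmid control. It called 7 genes, 4 higher (Il27, Ebi3, Hes1 and Dusp1) and 3 lower (Rn45s, Tnfaip3 and Zfp748), with 943 genes (7.78%) at an unadjusted p under 0.05. Hes1, Dusp1, Tnfaip3 and Zfp748 entered this average through IL27_pepL, since in IL27_scr alone their log2 fold changes were -0.16 ± 0.13, 0.07 ± 0.06, -0.05 ± 0.05 and -0.06 ± 0.07 (edgeR adjusted p = 0.999 for each). The count was 4 without plasmid control replicate 1 or 2 or any 1 of the IL27_scr libraries, 12 without IL27_pepL replicate 1 and 13 without IL27_pepL replicate 3. Preset camera passed 5 lists: interferon-stimulated genes (adjusted p = 0.0132), MHC class I genes and hypoxia and glycolysis genes (0.0036 for both) and ribosomal protein genes (1.26e-13) were higher and histone genes lower (9.82e-05), and with an estimated correlation the adjusted p was 0.841 for each. It passed 2 without plasmid control replicate 2, where the interferon, MHC class I and hypoxia lists had 0.796, 0.111 and 0.782; the hypoxia list had 0.0925 without IL27_pepL replicate 1, and the interferon list 0.475 without IL27_pepL replicate 2.

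Across genes, which are not independent replicates, the log2 fold changes of IL27_scr and IL27_pepL against the shared plasmid controls correlated with r = 0.53, against 0.51 ± 0.012 (SD) in 100 simulations of unchanged groups. Their covariance was 0.0181 against 0.00795 simulated, and without Il27 and Ebi3 it was 0.00738, again against 0.00795. Without these genes r was 0.32, below the simulated 0.51, and 58.1% of genes had the same sign in both comparisons against 66.9% simulated. The 3 calls of IL27_scr were also called in IL27_pepL in the same direction, where independent lists would share 0.00858 higher and 0.0120 lower and the simulations shared 0. The higher ones were Il27 and Ebi3, which both plasmids carry, so their overlap follows from the design. Without these genes 0 higher calls and 1 lower call, Rn45s, were shared. The comparisons of IL27_pepL with plasmid control and with IL27_scr share the IL27_pepL libraries; they shared 38 higher and 100 lower calls, where independent lists would share 0.566 and 2.08 and the simulations 0.01 each. Their correlation was 0.69 against 0.50 simulated and their covariance 0.0276 against 0.00770. With 3 libraries per group the shared group could not be split into parts of 2, and part of the excess may come from the shared libraries. Unchanged groups give almost no calls, so few shared calls in the simulations followed from their design. Genes were simulated as independent and without trends across genes, so the simulated spread may be too narrow.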

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

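The test of the transgene RNA amount and the divisions without Il27 and Ebi3 were chosen only after the result was seen; the offset for transcript length and GC content was added after the data were seen, before its own result was, and the spread that a value had to exceed in these tests was set with the results in view. The gene lists given here were picked out by preset camera. It called them lower in IL27_scr and higher in IL27_pepL, each against plasmid control, and called them in the direct comparison of the IL-27 groups as well. The median log2 difference was 0.57 for type I interferon-stimulated genes and 0.0936 for cytosolic and endosomal nucleic acid sensing genes. Camera gave adjusted p = 1.91e-44 and 1.24e-04 with the preset correlation and 0.114 and 0.188 with an estimated correlation. By gene, 26 of 32 and 5 of 20 members rose in the edgeR test and none fell. These lists are not separate: Irf7, Ddx58, Zbp1, Ifih1 and Dhx58 belong to both. Irf7, Ddx58 and Zbp1 are among the sensing calls, so the sensing list is not a second, independent result.

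For the interferon-stimulated genes, 3 technical readings and the design's own difference were weighed. A length and GC trend was argued against: with the offset the median was 0.57, unchanged from the value without it, and it ranged from 0.44 to 0.60 when 1 library was left out. Variation between libraries regardless of group could not be decided. Of the 280 ways to divide the 9 libraries into 3 groups of 3, 1 gave a between-group F as high as the real 14.9. That was the real one itself, or 0.357% (exact permutation, next highest 12.7). The list was picked out because its groups differed in these same libraries, so a high F was favoured beforehand and this share cannot argue against such variation. The amount of transgene RNA could not be decided either. Il27 in IL27_scr was 0.850 of its level in IL27_pepL, which in proportion would need a rise of 0.28 over plasmid control. The observed change was -0.20 with an upper one-sided exact 95% limit of -0.0314. The list was picked out in part for being lower in IL27_scr, so a change below 0 was favoured beforehand. These values therefore cannot argue against this reading, and Ebi3 was not used in the test. The peptide itself, the secreted protein amount and differences between plasmid preparations stay open as untested, so that the peptide may be the source is a hypothesis.

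Divisions of the same libraries were counted for each result. For genes, the real division gave 3, 197 and 306 calls in the 3 pairwise comparisons and the highest other 0 in each; the real one was the 1 of 10 with as many calls, and 10 divisions are too few for a share under 0.05. For both IL-27 groups against plasmid control the real 7 calls were reached by 1 of 100 drawn divisions (highest other 4), but Il27 and Ebi3 are among the 7 through the plasmids themselves. Without these genes, in a count chosen after the result was seen, the real division gave 3 calls and 2 of 100 divisions gave as many, the real one included. The highest other, with plasmid control replicates 2 and 3 and IL27_scr replicate 2 in place of the controls, gave 4. A division that kept the plasmid controls and regrouped the IL-27 libraries gave 1. The count thus depends on how the IL-27 libraries are grouped, so it cannot exclude chance for the contrast with plasmid control. For gene lists under preset camera the real counts of 6, 7 and 8 were reached by 5, 4 and 4 of 10 divisions (highest other 11, 10 and 11), again too few for a share under 0.05. With both IL-27 groups together the real 5 lists were reached by 61 of 100 divisions (highest other 14), and chance was not excluded.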

How the results depend on the processing

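All tests here were planned except the length and GC offset and the removal of Rn45s, which were chosen after the data were seen. Across alternatives, 5827 gene values, 1931 list values and 122 counts stayed on their side of the threshold or within 1.5 times; 87 and 47 gene and list values became called, 267 and 74 lost the call, 49 counts or correlations moved, and 2 list values reversed. DESeq2's Wald test called 774 genes in IL27_pepL against plasmid control (193 of the 197 among them), 811 against IL27_scr and 30 for both groups together. Fits of only the compared groups, with fewer samples to estimate the spread, called 48 and 165. Without Il27 and Ebi3 the counts were 1 in IL27_scr and 3 for both groups, and the correlation of fold changes was 0.319; without Rn45s both groups together gave 4. In the comparison of both groups the removed genes were themselves calls, and Dusp1 and Tnfaip3, each at adjusted p = 0.0470 with all genes, lost their calls in either setting. An estimated correlation passed 0 lists in each of the 4 comparisons, and fry passed 0, 0, 5 and 0. The cause of these changes was not tested further. Leaving out 1 library gave 3 to 3 genes for IL27_scr, 36 to 2084 for IL27_pepL, 69 to 1782 between the peptides and 4 to 13 for both groups; lists ranged over 3 to 9, 4 to 11, 5 to 11 and 2 to 7, and the correlation over 0.469 to 0.598. IL27_pepL replicate 1 gave both highest pairwise counts when omitted, plasmid control replicate 2 and IL27_scr replicate 2 the lowest (36 and 69). The reversed lists, both in IL27_scr against plasmid control and neither called with all libraries, were hypoxia and glycolysis without plasmid control replicate 2 (median -0.0347, adjusted p = 0.0135; 0.0451 at the other end of the range, without plasmid control replicate 1) and ribosomal protein genes without IL27_scr replicate 1 (0.0598, adjusted p = 3.28e-05; -0.0583 at the other end, without IL27_scr replicate 2); the cause was not tested. The absence of a filter and edgeR's own filter were the same setting here, since neither removed a gene. DESeq2 size factors gave 55 higher and 139 lower, and 141 and 165, in the IL27_pepL comparisons.

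Replicate numbers shared across groups were not taken to pair the samples, since nothing in the labels says that they do. Same-numbered libraries deviated together with r from -0.06 to 0.32. Of the 9 libraries, 4 correlated best with their own number in both other groups. These values do not decide whether the numbers pair, so a pairing stays open. As a block, replicate number gave 3, 1019, 1110 and 8 genes and 5, 7, 9 and 5 lists. With it 108 Zfp genes were lower and 0 higher in IL27_pepL against plasmid control, and 91 lower and 3 higher between the peptides. In the same comparisons 37 and 44 ribosomal protein genes were called, and 18 and 26 interferon-stimulated genes were called higher. The cause of the higher counts was not tested.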

Other observations

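All tests in this part were chosen only after the result was seen, except the length and GC tests, whose offset was added after the data were seen and before their own result was and whose predictions were written then; for the Zfp, ribosomal protein and Notch tests the spread that a value had to exceed was set with the results in view. Genes for zinc finger proteins with a Zfp symbol, a group defined after seeing the data, were lower in IL27_pepL. Of 323 measured (2.66% of genes), 64 fell against plasmid control, 44.1% of the 145 lower calls, and 60 fell against IL27_scr, 34.5% of the 174 lower calls; 0 rose in either. Without IL27_pepL replicate 2 the lower calls numbered 19 in each comparison, and without IL27_pepL replicate 1 they numbered 136 and 113, with 4 and 6 higher. Between the peptides 1 was higher with the length and GC offset. No p-value is given for this share, since the group was drawn from the same calls. The mean log2 CPM of the group was 3.94 ± 0.008 (SD, n = 3) in plasmid control, 3.92 ± 0.028 in IL27_scr and 3.72 ± 0.037 in IL27_pepL. Many of these genes belong to the KRAB zinc finger family of transcriptional repressors, whose similar sequences make single counts uncertain.

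The lower Zfp genes and the higher ribosomal protein genes of IL27_pepL go with a trend across all genes: against plasmid control the log2 fold change had a Spearman rho of -0.453 with transcript length and 0.281 with GC content, and against IL27_scr -0.371 and 0.291. With an offset that brings these close to 0, the Zfp median between the peptides went from -0.18 to -0.15. It ranged from -0.17 to -0.14 with 1 library left out. Without IL27_pepL replicate 3 the Zfp median was -0.15. These values argue against that trend, as measured on the longest annotated transcripts, or that library as the whole source. The ribosomal protein median went from 0.27 to 0.15 with the offset (0.11 to 0.20), so the trend may carry part of it. Whether the trend carries all of it cannot be decided, since the longest annotated transcript need not be the one expressed. Without IL27_pepL replicate 3 the ribosomal protein median was 0.18, with a range from 0.05 to 0.31 on leaving out a further library. This cannot decide how far that library sets it. An effect of the targeting peptide, and RNA quality, stay open as untested.

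Rn45s was lower in both IL-27 groups, at 0.373% and 0.364% of counts against 1.37% in plasmid control. Precursor ribosomal RNA and replication-dependent histone transcripts both lack a poly(A) tail, and a candidate explanation is a difference in the carry-over of such RNA at library preparation. The histone list was lower in both IL-27 groups together by -0.29 in mean log2 CPM (2-sided exact permutation p = 0.0476 over 84 divisions), the direction this explanation predicts. The test was chosen after the result was seen, so this p-value adds no independent support. For the histone list IL27_pepL replicate 3, at 1.30, lay at the plasmid control level of 1.30 ± 0.05. Snora65, a small nucleolar RNA that also lacks a tail, went the other way in IL27_pepL against plasmid control without passing (0.65 ± 0.17, edgeR adjusted p = 0.0718; -0.42 ± 0.19 in IL27_scr), though it lies within a host gene whose reads may count for it. A change in ribosomal RNA synthesis common to the IL-27 plasmids was not tested and stays open, and so does the carry-over.

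Hes1 is a known Notch target, and a hypothesis was that Notch output rose with the targeting peptide. Over 6 other measured Notch pathway genes the median log2 difference was 0.15, with a standard error of 0.11 taken from the spread of the genes, and 4 of 6 were above 0. Camera on the Notch list gave p = 0.995, and 0.996 with an estimated correlation, so no rise of the list was found. With members in both directions, Jag1 at -0.29 ± 0.08 and Hes6 at 0.28 ± 0.16, the test cannot decide between a pathway response and a change in Hes1 by another route.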
